A study of Mus musculus with 12 samples.

How the data were processed

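RNA of ileum and synovium was measured in 12 libraries, 3 biological replicates for each tissue of TNFdARE mice and of WT littermates. Per the labels, RNA was isolated with the RNeasy Micro kit, poly-A RNA was made into stranded libraries with the TruSeq Stranded mRNA kit, and single reads of 100 cycles were sequenced from an equimolar pool on an Illumina NovaSeq. The authors' processing notes name cutadapt 1.15, Bowtie2 2.3.3.1 and the GRCm38 build; the counting tool and the annotation release are not given in the sources used here. The authors deposited raw counts per Ensembl gene for 46603 genes, of which 19236 had 0 counts in every library. They also deposited FPKM for 17046 genes. Checked against the counts, the deposited FPKM had been adjusted further in a way the sources do not state: none was 0, although 5756 of these values belonged to a count of 0, and the ratio of FPKM to count followed GC content across genes (Pearson r between 0.11 and 0.52 in the ileum and between -0.59 and -0.21 in the synovium). In 265 genes of the ileum and 328 of the synovium all 6 libraries shared a single FPKM value. Prg4 was among these, with an FPKM of 1923 in each synovium library while its counts ran from 58820 to 231981. The counts were therefore used for the comparisons and the FPKM served as an alternative.

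Symbols and coordinates came from the GENCODE annotation of GRCm38 by gene identifier, which matched 98.7% of the identifiers of the count table. Library totals lay between 14267834 and 16224402 counts, and a count of 0 allows up to 3 counts of a library's total, between 0.185 and 0.210 CPM before TMM. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

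Each tissue was fitted by itself in R 4.3.3 with edgeR 4.0.16 on its 6 libraries: genes were filtered by filterByExpr with the genotype groups, scaled by TMM and tested by the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The difference of effects between tissues was tested as an interaction in a model of the 4 groups over all 12 libraries. Every adjusted p of a gene comes from edgeR unless another tool is named. CPM used the TMM-scaled library sizes.

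The 46 gene lists covered signalling pathways, immune cells, epithelium, stroma, and tissues that a dissection can carry along; 24 of them were tested in both tissues. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes and adjusted over the lists of a tissue, which made 34 tests in the ileum, 35 in the synovium and 24 for the interaction. Camera was repeated with an estimated correlation, and fry tested whether the genes of a list moved, on balance, in 1 direction. Lists shared members: 10 of 19 neutrophil genes, 10 of 20 chemokine ligands and 5 of 20 TNF and NF-kB target genes stood in another list too. The numbers of members past the threshold are given over all genes and adjusted over the list alone.

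The comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule named Tnf, Foxp3 and Il10. In each tissue it added the 5 largest increases and the 5 largest decreases among called genes with a mean log2 CPM of at least 1, no overlap between groups and a proper symbol, immunoglobulin and T cell receptor segments excepted. From each list that passed, or had at least 3 called members, it took the 2 called members with the smallest adjusted p. For a list with none called it took the most abundant member. The interaction followed the same rule without the overlap condition. Not every gene that the rule selected is reported here.

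Replicate numbers were checked as a possible pairing on 11785 genes with a mean log2 CPM above 3, by correlating deviations from the group mean across autosomal genes. Equal numbers of TNFdARE and WT correlated at 0.215, 0.239 and 0.166 in the ileum and at 0.458, 0.293 and 0.180 in the synovium. Sex as read from the counts followed the numbers. A fit with replicate number as a block is therefore given where it changed a call. Across tissues equal numbers correlated between -0.103 and 0.137, so a block by animal was kept as an alternative only. Between replicates of a group, counts differed by 11.2 to 92.9 times the Poisson variance per gene, so no pair of libraries held the same reads.

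The procedure was tested on simulated data. Each gene had its mean over both genotypes of a tissue and the spread fitted over all libraries of the comparison. Both genotypes were given the same spread, and genes were drawn independently. The procedure recovered 60.6% of 2-fold and 88.4% of 4-fold changes in the ileum, 63.3% and 89.7% in the synovium, and 38.8% and 72.7% for the interaction, with 11 false calls of 155, 11 of 160 and 3 of 113. With no change simulated it made 1, 0 and 0 calls.

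The alternatives were RLE factors, library size only, no filter, a filter of 10 counts, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), an adjusted p under 0.01, a 2-fold minimum, replicate or animal as a block, a fit of all 12 libraries, and leaving out each library in turn. Fits with sex or with the muscle level as a covariate, the overlap without single libraries, and the interaction lists without ileum TNFdARE replicate 2, were added after seeing the data. No library was left out of the comparisons.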

Results

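Ileum and synovium were taken from TNFdARE mice and from their WT littermates, and each tissue of each genotype was sequenced as 3 biological replicates, which made 12 libraries in 4 groups. TNFdARE mice carry a Tnf gene without the AU-rich element of its 3' untranslated region, a sequence that limits Tnf mRNA stability and translation, and they are known to develop ileitis and arthritis. The series title places the samples in a study of regulatory T cells in gut and joint inflammation. The labels give neither age nor sex, and they do not say whether both tissues came from the same animals. In the ileum the libraries of poly-A RNA held 15546766, 14371302 and 14267834 counts for TNFdARE replicates 1, 2 and 3, and 15700665, 14661925 and 15401644 for WT. In the synovium they held 16224402, 16185608 and 16146694 counts for TNFdARE and 14824011, 15004725 and 14289975 for WT. Levels are given as CPM, counts scaled to the library total after TMM, and before TMM a single count corresponded to between 0.0616 and 0.0701 CPM. Counts of the transcript Xist and of 4 genes of the Y chromosome placed replicate 3 of each group with females and replicates 1 and 2 with males. Fold changes below are on the log2 scale with their standard error (SE), and CPM values are means with the standard deviation (SD) of 3 libraries.

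Tnf itself, the modified gene, was examined first, because its level tests the genotype labels. Tnf (ENSMUSG00000024401, GRCm38 chromosome 17, 35199381 to 35202007, minus strand) reached 47.4 ± 31.8 CPM in TNFdARE and 1.81 ± 0.638 CPM in WT ileum (n = 3 each), a log2 fold change of 4.70 ± 0.68 (adjusted p = 0.0404). In the synovium it reached 34.7 ± 5.09 CPM in TNFdARE and 2.08 ± 0.119 CPM in WT, a log2 fold change of 4.06 ± 0.15 (adjusted p = 6.18e-05). Every TNFdARE library lay above every WT library of its tissue. The 3 TNFdARE ileum libraries were unequal, at 80.005, 16.5 and 45.7 CPM of Tnf in replicates 1, 2 and 3. The ileum call of Tnf ended without TNFdARE replicate 3 (4.73, adjusted p = 0.155) and without WT replicate 1, 2 or 3 (5.02, 4.52 and 4.60, adjusted p = 0.153, 0.150 and 0.174), and it kept its direction in all of these. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), the transcription factor of regulatory T cells, rose in the ileum by 3.13 ± 0.56 (5.99 ± 3.19 CPM in TNFdARE and 0.677 ± 0.343 CPM in WT, adjusted p = 0.041). In the synovium Foxp3 rose by 1.86 ± 0.48 (2.42 ± 0.619 CPM in TNFdARE and 0.655 ± 0.383 CPM in WT, adjusted p = 0.031). The synovium call of Foxp3 ended without TNFdARE replicate 1 or 2 (adjusted p = 0.0793 and 0.0747) and without WT replicate 2 or 3 (0.0508 and 0.0633), and it ended with sex (0.0505) or muscle level (0.229) as a covariate, both added after the data were seen. Without ileum TNFdARE replicate 1 its ileum call ended as well (2.71, adjusted p = 0.0515), as it did without replicate 3 or any WT library (adjusted p between 0.152 and 0.175), with limma-voom (0.0796), with the FPKM fits (0.0576 to 0.0846) and with sex as covariate (0.0962). Il10, the gene of an anti-inflammatory cytokine, had 3 to 11 counts in TNFdARE and 1 to 3 in WT ileum, and 7 to 20 in TNFdARE and 2 to 6 in WT synovium. These counts were too low for Il10 to be tested within either tissue.

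**Figure D1:**
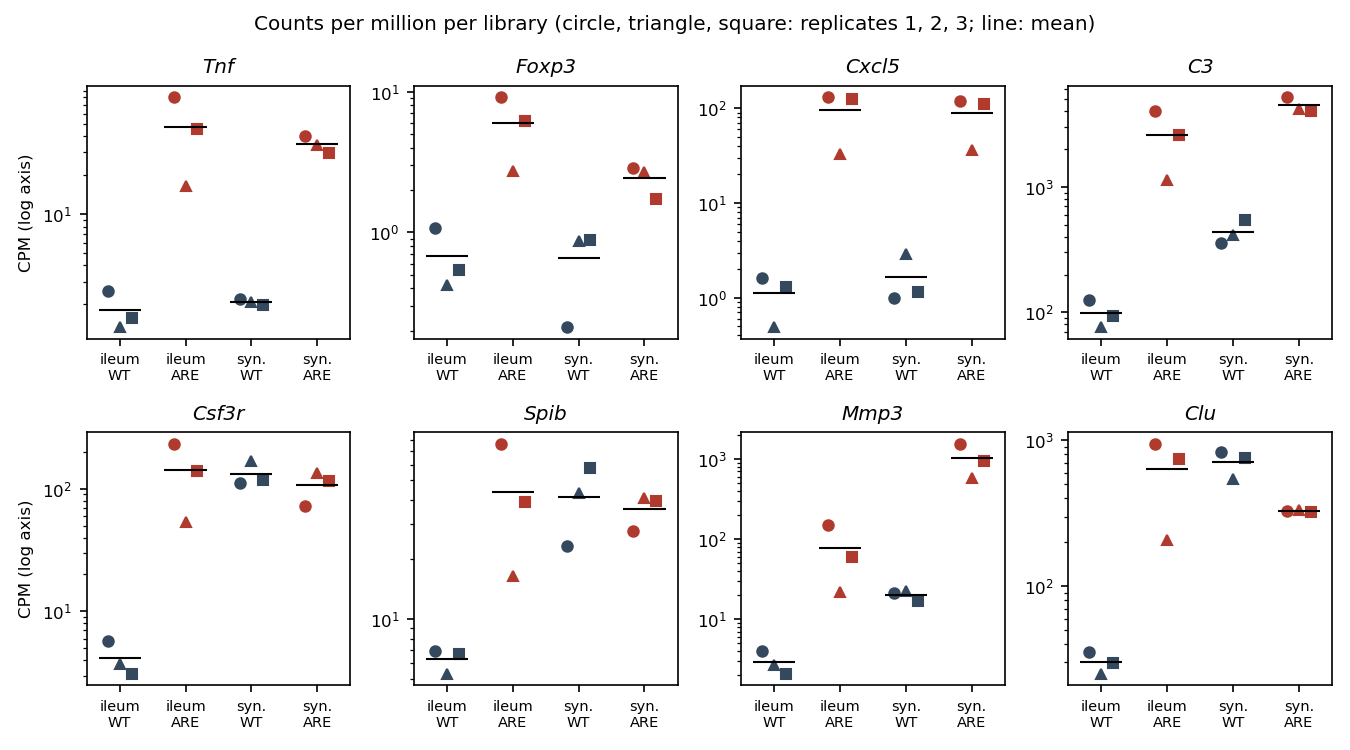
CPM of 8 genes in each library on a log axis, by tissue and genotype (ARE stands for TNFdARE). Circles, triangles and squares are replicates 1, 2 and 3, and the line is the mean of 3 libraries. Tnf lies above WT in every TNFdARE library of both tissues, while Csf3r does so in ileum and Clu is higher in TNFdARE ileum and lower in TNFdARE synovium.

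The first comparison asked which transcripts differed between TNFdARE and WT ileum. Cxcl5, a chemokine that attracts neutrophils, rose from 1.13 ± 0.572 to 95.5 ± 54.7 CPM (6.39 ± 0.75, adjusted p = 0.0389). Csf3r, the receptor of granulocyte colony-stimulating factor, rose by 5.07 ± 0.64 (adjusted p = 0.0389) and C3, the central complement component, by 4.72 ± 0.53 (2577 ± 1431 CPM in TNFdARE and 98 ± 24.3 CPM in WT, adjusted p = 0.0389). Of 15462 genes tested, 637 rose and 242 fell at an adjusted p under 0.05, and 453 and 50 of them changed at least 2-fold. CPM of the 3 TNFdARE and 3 WT libraries did not overlap in any of the called genes, so each change was seen in all 3 TNFdARE libraries; over all genes tested 37.3% did not overlap, where chance gives 10%.

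Among called genes with a proper symbol and a mean log2 CPM of at least 1, the 5 largest increases were in S100a8 and S100a9, the subunits of calprotectin, in Il1f9 and Gpr84, and in Acod1, the enzyme of itaconate synthesis in activated macrophages. All 5 were near the floor in WT ileum. Summed over the group, Acod1 had 2753 counts in TNFdARE and 2 in WT, a ratio of count shares of 1430 (95% exact interval of counting error 394 to 11800). The ratio was 163 (55.3 to 791) for Gpr84, 308 (54.8 to 12200) for Il1f9, 363 (142 to 1340) for S100a8 and 228 (127 to 458) for S100a9. TNFdARE replicate 2 held 72 of the Acod1 counts, against 2134 and 547 in replicates 1 and 3. Within these limits the 5 largest decreases were in Acta1, the actin of skeletal muscle (-3.40 ± 0.67), Cyp4b1 (-2.42 ± 0.37, adjusted p = 0.0404), B3gnt7 (-2.29 ± 0.40), Fst, the gene of follistatin (-1.94 ± 0.41), and Thpo, the gene of thrombopoietin (-1.94 ± 0.33). With replicate number as a block the call was lost for Acta1 (-3.25, adjusted p = 0.068) and Fst (-1.98, adjusted p = 0.069).

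Fixed lists of immune genes moved upward in the ileum. Of 18 TNF and NF-kB target genes tested, 8 rose, 0 fell and 10 did not pass (adjusted over the list alone, 18 and 0), with a median of 2.21 (camera adjusted p = 3.29e-14, and adjusted p = 0.304 with an estimated correlation). They included Ccl2, a chemokine for monocytes (4.05 ± 0.54), and Cxcl5. Among the neutrophil markers, 8 of 11 rose and 0 fell, and 3 did not pass (adjusted over the list alone, 10 and 0); the median was 4.86 (camera adjusted p = 6.44e-11, and adjusted p = 0.304 with an estimated correlation). Mmp9, a gelatinase stored in neutrophil granules, rose by 3.99 ± 0.27 and had the smallest adjusted p of the named genes (0.0305). Of 20 markers of monocytes and macrophages tested, 8 rose, 0 fell and 12 did not pass (adjusted over the list alone, 17 and 1), with a median of 1.93 (camera adjusted p = 1.51e-10, and adjusted p = 0.304 with an estimated correlation). Lyz2, the lysozyme of myeloid cells, rose by 4.21 ± 0.68 and Csf1r, the receptor of macrophage colony-stimulating factor, by 2.57 ± 0.39. Among the dendritic cell markers, 6 of 15 rose and 0 fell, and 9 did not pass (adjusted over the list alone, 12 and 0); the median was 1.48 (camera adjusted p = 2.93e-09, and adjusted p = 0.304 with an estimated correlation). Itgax (CD11c) rose by 2.70 ± 0.37 and Flt3 by 2.50 ± 0.42. The complement genes had a median of 1.97 over 15 tested members, of which 9 rose, 0 fell and 6 did not pass (adjusted over the list alone, 12 and 1; camera adjusted p = 1.51e-10, and adjusted p = 0.304 with an estimated correlation). C1s1, a serine protease of the classical pathway, rose by 2.01 ± 0.24. Of 19 chemokine ligands tested, 6 rose, 0 fell and 13 did not pass (adjusted over the list alone, 10 and 2), with a median of 1.82 (camera adjusted p = 1.75e-04, and adjusted p = 0.304 with an estimated correlation). Among the IL-17 and IL-23 axis genes, 3 of 12 rose and 1 fell, and 8 did not pass (adjusted over the list alone, 7 and 1); the median was 1.66 (camera adjusted p = 0.00189, and adjusted p = 0.304 with an estimated correlation). Il22ra2, a soluble decoy receptor of IL-22, rose by 3.45 ± 0.44.

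Most lymphocyte lists also moved upward. Of 18 regulatory T cell markers tested, 7 rose, 0 fell and 11 did not pass (adjusted over the list alone, 15 and 0), with a median of 1.17 (camera adjusted p = 2.51e-09, and adjusted p = 0.304 with an estimated correlation). Besides Foxp3 they included Ebi3, a subunit of IL-35 and IL-27 (2.17 ± 0.37), and Tnfrsf9, the receptor 4-1BB (2.53 ± 0.38). Among the T cell co-inhibition and exhaustion genes, 3 of 13 rose and 0 fell, and 10 did not pass (adjusted over the list alone, 8 and 1); the median was 1.43 (camera adjusted p = 4.08e-05, and adjusted p = 0.304 with an estimated correlation). Havcr2 (TIM-3) rose by 1.92 ± 0.28 and Cd86, a ligand of CD28 and CTLA-4 on antigen-presenting cells, by 1.82 ± 0.30. The T cell markers had a median of 0.69 over 19 tested members, of which 1 rose, 0 fell and 18 did not pass (adjusted over the list alone, 6 and 0; camera adjusted p = 7.48e-04, and adjusted p = 0.475 with an estimated correlation). The member that rose was Cd28 (1.37 ± 0.21). Among the B cell markers, 1 of 11 rose and 0 fell, and 10 did not pass (adjusted over the list alone, 11 and 0); the median was 2.79 (camera adjusted p = 6.90e-05, and adjusted p = 0.352 with an estimated correlation). It was Spib, a transcription factor of B cells that plasmacytoid dendritic cells and M cells also express (2.79 ± 0.57). Of 9 germinal centre and lymphoid follicle genes tested, 2 rose, 0 fell and 7 did not pass (adjusted over the list alone, 8 and 0), with a median of 2.46 (camera adjusted p = 2.43e-06, and adjusted p = 0.304 with an estimated correlation). These were Cxcl13, the chemokine that draws B cells into follicles (3.03 ± 0.50), and Clu, which follicular dendritic cells and regenerating epithelium express (4.39 ± 0.60). The plasma cell markers had a median of 0.99 over 16 tested members, of which 0 rose, 0 fell and 16 did not pass (adjusted over the list alone, 5 and 0; camera adjusted p = 2.49e-04, and adjusted p = 0.38 with an estimated correlation). Igha, the constant region of IgA, had a log2 fold change of 1.00 ± 0.36 (adjusted p = 0.123). Immunoglobulin genes took 3.07%, 1.19% and 2.15% of the counts in TNFdARE replicates 1, 2 and 3, and 1.03%, 0.692% and 1.12% in WT.

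Other lists shared by both tissues moved in the ileum as well. Among the interferon-gamma response and MHC class II genes, 0 of 19 rose and 0 fell, and 19 did not pass (adjusted over the list alone, 0 and 0); the median was 1.07 (camera adjusted p = 4.75e-04, and adjusted p = 0.475 with an estimated correlation). Cd74, the invariant chain of MHC class II, had a log2 fold change of 1.07 ± 0.57 (adjusted p = 0.259), and it passed with the replicate block (0.99, adjusted p = 0.039). Of 15 matrix metalloproteinases and aggrecanases tested, 4 rose, 1 fell and 10 did not pass (adjusted over the list alone, 7 and 2), with a median of 0.57 (camera adjusted p = 7.48e-04, and adjusted p = 0.304 with an estimated correlation). Mmp12, the elastase of macrophages, rose by 5.36 ± 0.85. The extracellular matrix and fibroblast activation genes had a median of 0.31 over 18 tested members, of which 5 rose, 0 fell and 13 did not pass (adjusted over the list alone, 6 and 0; camera adjusted p = 0.0123, and adjusted p = 0.304 with an estimated correlation). Col1a2 rose by 0.66 ± 0.10 and Timp1 by 3.05 ± 0.50; without TNFdARE replicate 2 this list's call ended (adjusted p = 0.0966). Among the oxidative phosphorylation genes, 0 of 16 rose and 2 fell, and 14 did not pass (adjusted over the list alone, 0 and 15); the median was -0.33 (camera adjusted p = 2.02e-07, and adjusted p = 0.304 with an estimated correlation). Cytochrome c, Cycs, fell by 0.81 ± 0.10 and Cox5a by 0.49 ± 0.09. Of 18 cell cycle genes tested, 0 rose, 1 fell and 17 did not pass (adjusted over the list alone, 0 and 3), with a median of -0.10 (camera adjusted p = 0.0293, and adjusted p = 0.304 with an estimated correlation). Tyms, thymidylate synthase, had -0.42 ± 0.08. Tyms lost its call with the replicate block (-0.42, adjusted p = 0.059). The Cell cycle list lost it with the block (adjusted p = 0.074), with all 12 libraries (0.188), without TNFdARE replicate 2 or 3 (0.119 and 0.0822) and with library size only (0.0995), where its median was 0.01. Among the immediate early and heat shock genes, 0 of 14 rose and 1 fell, and 13 did not pass (adjusted over the list alone, 1 and 6); the median was -0.18 (camera adjusted p = 0.027, and adjusted p = 0.304 with an estimated correlation). Hsph1, a heat shock protein, was the member that fell (-1.69 ± 0.29), and the list's call ended without TNFdARE replicate 2 (adjusted p = 0.225).

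Epithelial lists that passed moved downward except for the tuft cells, with few members past the threshold. Of 18 absorptive enterocyte and nutrient uptake genes tested, 0 rose, 0 fell and 18 did not pass (adjusted over the list alone, 1 and 8), with a median of -0.85 (camera adjusted p = 1.66e-06, and adjusted p = 0.304 with an estimated correlation). Anpep, a brush border peptidase, had -1.26 ± 0.36 (adjusted p = 0.0802). Among the lipid and xenobiotic metabolism genes of the enterocyte, 1 of 19 rose and 3 fell, and 15 did not pass (adjusted over the list alone, 1 and 8); the median was -0.73 (camera adjusted p = 3.37e-06, and adjusted p = 0.304 with an estimated correlation). Dgat2, an enzyme of triglyceride synthesis, rose by 0.63 ± 0.10, while Acsl5, a long-chain acyl-CoA synthetase, had -0.47 ± 0.08 and lost its call with the block (adjusted p = 0.051). The ileal bile acid handling genes had a median of -0.59 over 10 tested members, of which 0 rose, 0 fell and 10 did not pass (adjusted over the list alone, 1 and 4; camera adjusted p = 0.0236, and adjusted p = 0.42 with an estimated correlation). This call ended with the block (adjusted p = 0.524) and without WT replicate 3 (0.0677), and Fabp6, the ileal bile acid binding protein, had -0.02 ± 0.27 (adjusted p = 0.963). Of 14 Paneth cell markers tested, 0 rose, 0 fell and 14 did not pass (adjusted over the list alone, 0 and 0), with a median of -1.45 (camera adjusted p = 1.66e-06, and adjusted p = 0.346 with an estimated correlation). Lyz1, the Paneth cell lysozyme, had -1.51 ± 0.51 (1680 ± 1056 CPM in TNFdARE and 4779 ± 1042 CPM in WT, adjusted p = 0.114). Among the goblet cell and mucus genes, 0 of 15 rose and 1 fell, and 14 did not pass (adjusted over the list alone, 0 and 1); the median was -0.38 (camera adjusted p = 0.00189, and adjusted p = 0.352 with an estimated correlation). Muc3, a membrane mucin, had -1.09 ± 0.18. The enteroendocrine cell markers had a median of -0.39 over 14 tested members, of which 0 rose, 0 fell and 14 did not pass (adjusted over the list alone, 0 and 0; camera adjusted p = 0.00133, and adjusted p = 0.315 with an estimated correlation). Chgb, a granin of hormone granules, had -0.54 ± 0.25 (adjusted p = 0.196). Among the gut smooth muscle and enteric nervous system genes, 0 of 16 rose and 0 fell, and 16 did not pass (adjusted over the list alone, 0 and 0); the median was -0.40 (camera adjusted p = 5.29e-04, and adjusted p = 0.352 with an estimated correlation). Myh11, smooth muscle myosin, had -0.42 ± 0.20 (adjusted p = 0.214). Of 11 tuft cell markers tested, 3 rose, 0 fell and 8 did not pass (adjusted over the list alone, 4 and 0), with a median of 0.25 (camera adjusted p = 0.013, and adjusted p = 0.304 with an estimated correlation). These included Ltc4s (1.76 ± 0.35), which myeloid cells express too, and without TNFdARE replicate 2 the list's call ended (adjusted p = 0.0614).

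Lists of 7 further kinds did not pass in the ileum. Of 17 antimicrobial and dual-oxidase epithelium genes tested, 4 rose, 1 fell and 12 did not pass (adjusted over the list alone, 4 and 4), with a median of 0.14 (camera adjusted p = 0.6). Saa3, an acute-phase serum amyloid A, rose by 5.70 ± 0.86. The test of this list pointed down while its median and its mean of 0.91 were positive, and with the replicate block it passed upward (median 0.0036, adjusted p = 0.0265). Among the type I interferon response genes, 0 of 19 rose and 0 fell, and 19 did not pass (adjusted over the list alone, 0 and 0); the median was -0.02 (camera adjusted p = 0.743). Their mean was 0.05 and their test pointed down, and Oasl2 had -0.02 ± 0.60. The cytotoxic and NK cell markers had a median of 0.36 over 12 tested members, of which 0 rose, 0 fell and 12 did not pass (adjusted over the list alone, 0 and 0; camera adjusted p = 0.743). Gzma, granzyme A, had -0.76 ± 0.49. Among the mast cell and eosinophil markers, 1 of 6 rose and 0 fell, and 5 did not pass (adjusted over the list alone, 3 and 0); the median was 0.69 (camera adjusted p = 0.0528). That list passed without TNFdARE replicate 1 or 3 (adjusted p = 0.0204 and 0.0482) and without WT replicate 3 (0.0466). Of 14 endothelial markers tested, 1 rose, 0 fell and 13 did not pass (adjusted over the list alone, 4 and 0), with a median of 0.14 (camera adjusted p = 0.217). Among the red blood cell genes, 0 of 6 rose and 0 fell, and 6 did not pass (adjusted over the list alone, 0 and 0); the median was -0.13 (camera adjusted p = 0.386). The crypt stem cell markers had a median of -0.11 over 12 tested members, of which 0 rose, 0 fell and 12 did not pass (adjusted over the list alone, 0 and 0; camera adjusted p = 0.385). Olfm4, a crypt stem cell marker, had 0.04 ± 0.20, and Hbb-bs, a beta globin, had 0.05 ± 0.33. Of 12 genes listed for the Exocrine pancreas only Cela1 was tested (-0.05 ± 0.22), so that list had no test.

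The 27 ileum list calls all ended with an estimated correlation, and fry called 3 lists upward and 0 downward. TNFdARE replicate 2 lay nearest to WT: on the principal component that held 65.7% of the ileum variance it stood at 1.19, the other TNFdARE libraries at -84.0 and -52.5, and WT between 37.4 and 51.3. In a measure added after the data were seen, it kept a median share of -0.0131 of the shift of the other 2 TNFdARE libraries over 14 T cell markers, -0.0614 over 9 interferon-gamma response and MHC class II genes and 0.0403 over 11 B cell markers, all called without it, so the rise of these lists rests on TNFdARE replicates 1 and 3. Without it 2609 genes rose and 2024 fell; without TNFdARE replicate 1 the counts were 213 and 65, without replicate 3 they were 2 and 0, and without any one WT library both were 0, with none of the 42 named called genes kept in the last 4 cases. In the ileum 4715 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0305, and limma-voom called 0 genes either way, DESeq2 1715 higher and 988 lower, library size without a further factor 1218 and 161, and a fit with sex as covariate 0 and 0.

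The second comparison asked the same of TNFdARE and WT synovium. Saa3 rose from 0.926 ± 0.675 to 338 ± 143 CPM (n = 3 each; 8.51 ± 0.64, adjusted p = 0.00115) and Ccl2 from 2.19 ± 1.20 to 190 ± 15.2 CPM (6.45 ± 0.38, adjusted p = 5.30e-04). Mmp3, stromelysin, an enzyme that degrades cartilage matrix, rose by 5.67 ± 0.43 (1020 ± 483 CPM in TNFdARE and 20.1 ± 3.01 CPM in WT, adjusted p = 9.99e-04). Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165), the gene of the joint lubricant lubricin, had 3896 ± 340 CPM in TNFdARE and 14225 ± 1278 CPM in WT, a log2 fold change of -1.87 ± 0.13 (adjusted p = 4.19e-04). Of 15599 genes tested, 2037 rose and 1676 fell, and 613 and 643 of them changed at least 2-fold. The groups did not overlap in 99.97% of the called genes and in 44.5% of all genes tested, where chance gives 10%.

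Among called genes within the same limits, the 5 largest increases were in Saa3, Ccl2, Cxcl13 (6.36 ± 0.42, adjusted p = 4.60e-04), Bdkrb1, the inducible bradykinin receptor (5.85 ± 0.47, adjusted p = 5.39e-04), and Cryaa, an alpha crystallin. Cryaa had 411 counts over the TNFdARE libraries and 2 over the WT libraries, a ratio of count shares of 187 (95% exact interval of counting error 51.4 to 1550). Within them the 5 largest decreases were in Itgad, an integrin of macrophages (-5.09 ± 0.79, adjusted p = 0.00714), Serpinb7 (-3.23 ± 0.37), Coch, cochlin (-3.20 ± 0.72), Htra4, a serine protease (-2.36 ± 0.25), and Ffar1, a fatty acid receptor (-2.36 ± 0.43). Htra4 was the most abundant of these, with 62.3 ± 20.8 CPM in TNFdARE and 319 ± 41.4 CPM in WT.

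Several inflammatory and myeloid lists moved upward in the synovium. Of 20 TNF and NF-kB target genes tested, 18 rose, 0 fell and 2 did not pass (adjusted over the list alone, 19 and 0), with a median of 1.57 (camera adjusted p = 3.35e-35, and adjusted p = 0.0456 with an estimated correlation). Among all 35 lists, that call alone held with an estimated correlation; it included Tnfaip3, the inhibitor A20 (1.73 ± 0.09), and Traf1 (2.26 ± 0.09). Among the chemokine ligands, 13 of 19 rose and 1 fell, and 5 did not pass (adjusted over the list alone, 13 and 1); the median was 3.06 (camera adjusted p = 1.40e-19, and adjusted p = 0.0925 with an estimated correlation). Cx3cl1, fractalkine, rose by 2.54 ± 0.13 and Cxcl16 by 3.06 ± 0.19. The markers of monocytes and macrophages had a median of 1.19 over 20 tested members, of which 14 rose, 0 fell and 6 did not pass (adjusted over the list alone, 15 and 1; camera adjusted p = 7.20e-18, and adjusted p = 0.103 with an estimated correlation). Ccr2, the receptor of CCL2, rose by 1.90 ± 0.08 and Csf1r by 1.14 ± 0.08. Of 15 complement genes tested, 11 rose, 1 fell and 3 did not pass (adjusted over the list alone, 13 and 1), with a median of 1.37 (camera adjusted p = 7.01e-15, and adjusted p = 0.13 with an estimated correlation). C3 rose by 3.35 ± 0.20 and C1qc by 1.24 ± 0.10. Among the interferon-gamma response and MHC class II genes, 12 of 18 rose and 0 fell, and 6 did not pass (adjusted over the list alone, 13 and 0); the median was 1.00 (camera adjusted p = 5.21e-11, and adjusted p = 0.13 with an estimated correlation). Gbp5 rose by 1.61 ± 0.11 and H2-DMb1 by 1.46 ± 0.12. The dendritic cell markers had a median of 0.39 over 14 tested members, of which 6 rose, 0 fell and 8 did not pass (adjusted over the list alone, 6 and 0; camera adjusted p = 0.00314, and adjusted p = 0.334 with an estimated correlation). Itgax rose by 1.73 ± 0.08 and Sirpa by 0.95 ± 0.10. Of 15 matrix metalloproteinases and aggrecanases tested, 10 rose, 1 fell and 4 did not pass (adjusted over the list alone, 10 and 1), with a median of 1.05 (camera adjusted p = 8.68e-06, and adjusted p = 0.321 with an estimated correlation). Mmp19 rose by 2.01 ± 0.21.

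Cell cycle and lymphocyte lists went both ways. Among the cell cycle genes, 9 of 18 rose and 0 fell, and 9 did not pass (adjusted over the list alone, 17 and 0); the median was 1.13 (camera adjusted p = 2.19e-06, and adjusted p = 0.443 with an estimated correlation). Cdk1 rose by 1.43 ± 0.27 and Ccnb1, cyclin B1, by 1.37 ± 0.28. Of 18 regulatory T cell markers tested, 7 rose, 1 fell and 10 did not pass (adjusted over the list alone, 7 and 1), with a median of 0.72 (camera adjusted p = 0.00214, and adjusted p = 0.13 with an estimated correlation). Besides Foxp3 they included Il1rl1, the receptor of IL-33 (1.41 ± 0.11), and Entpd1, the ectonucleotidase CD39 (0.52 ± 0.10), both of which other cell types express too. The T cell co-inhibition and exhaustion genes had a median of 0.65 over 12 tested members, of which 5 rose, 2 fell and 5 did not pass (adjusted over the list alone, 6 and 2; camera adjusted p = 0.00476, and adjusted p = 0.139 with an estimated correlation). Havcr2 rose by 2.10 ± 0.15 and Cd274 (PD-L1) by 1.09 ± 0.14. Among the T cell markers, 1 of 19 rose and 4 fell, and 14 did not pass (adjusted over the list alone, 1 and 4); the median was -0.61 (camera adjusted p = 0.0331, and adjusted p = 0.443 with an estimated correlation). Cd4, which mouse monocytes and macrophages can also express at a low level, rose by 0.86 ± 0.12, and Cd8a had -1.54 ± 0.29. The T cells call ended with the replicate block (adjusted p = 0.0952), without TNFdARE replicate 1 (0.0821) and without WT replicate 1 or 3 (0.0674 and 0.0654). Of 14 B cell markers tested, 1 rose, 2 fell and 11 did not pass (adjusted over the list alone, 1 and 8), with a median of -1.06 (camera adjusted p = 0.00637, and adjusted p = 0.587 with an estimated correlation). Cxcr5, the follicle homing receptor, had -2.13 ± 0.52, and Cd72 rose by 1.03 ± 0.20. Among the mast cell and eosinophil markers, 0 of 12 rose and 2 fell, and 10 did not pass (adjusted over the list alone, 0 and 3); the median was -0.84 (camera adjusted p = 0.0235, and adjusted p = 0.443 with an estimated correlation). Tpsab1, a tryptase, had -1.69 ± 0.41 and Ccr3 had -1.42 ± 0.38, and the call ended without WT replicate 2 or 3 (adjusted p = 0.0653 and 0.0571). The type I interferon response genes had a median of -0.45 over 19 tested members, of which 1 rose, 6 fell and 12 did not pass (adjusted over the list alone, 1 and 6; camera adjusted p = 0.00486, and adjusted p = 0.577 with an estimated correlation). Ifit2 had -0.53 ± 0.09 and Mx2 -0.89 ± 0.21. With all 12 libraries the type I interferon call ended (adjusted p = 0.0787), as did that of the B cells (0.184), and with fry the calls of type I interferon (0.102), B cells (0.158), mast cells and eosinophils (0.0783) and the cell cycle (0.0625) ended.

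Several lists of resident tissue moved downward. Of 15 adipocyte markers tested, 0 rose, 13 fell and 2 did not pass (adjusted over the list alone, 0 and 14), with a median of -1.25 (camera adjusted p = 2.52e-10, and adjusted p = 0.298 with an estimated correlation). Pparg, the regulator of fat cell differentiation, had -1.25 ± 0.16 and Pnpla2, a triglyceride lipase, -1.16 ± 0.15. Among the markers of synovial lining fibroblasts, 2 of 14 rose and 9 fell, and 3 did not pass (adjusted over the list alone, 2 and 10); the median was -0.72 (camera adjusted p = 7.15e-06, and adjusted p = 0.139 with an estimated correlation). Prg4 belonged to those that fell and Mmp3 to those that rose. The chondrocyte and cartilage genes had a median of -1.24 over 15 tested members, of which 0 rose, 6 fell and 9 did not pass (adjusted over the list alone, 0 and 11; camera adjusted p = 1.59e-05, and adjusted p = 0.373 with an estimated correlation). Chad, chondroadherin, had -1.89 ± 0.29 and Comp, a cartilage matrix protein, -0.62 ± 0.12. Of 15 osteoblast and bone matrix genes tested, 0 rose, 8 fell and 7 did not pass (adjusted over the list alone, 0 and 10), with a median of -0.83 (camera adjusted p = 4.40e-05, and adjusted p = 0.429 with an estimated correlation). Runx2, the transcription factor of osteoblasts, had -0.62 ± 0.11 and Alpl, alkaline phosphatase, -0.84 ± 0.18. Among the skeletal muscle genes, 0 of 17 rose and 1 fell, and 16 did not pass (adjusted over the list alone, 0 and 14); the median was -1.65 (camera adjusted p = 1.31e-05, and adjusted p = 0.443 with an estimated correlation). Myh4, a fast myosin, was the member that fell (-1.77 ± 0.46). The mean log2 CPM of the muscle list was 8.95, 8.02 and 7.001 in TNFdARE replicates 1, 2 and 3 and 10.46, 9.34 and 9.67 in WT, so the amount of muscle RNA moved with genotype in the same libraries as the adipocyte, cartilage and bone genes. The oxidative phosphorylation genes had a median of -0.25 over 16 tested members, of which 0 rose, 1 fell and 15 did not pass (adjusted over the list alone, 0 and 0; camera adjusted p = 0.0331, and adjusted p = 0.673 with an estimated correlation). Sdha, a subunit of succinate dehydrogenase, was the member that fell (-0.34 ± 0.08), and the list's call ended without TNFdARE replicate 3 (adjusted p = 0.0537) and without WT replicate 1 (0.133).

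Lists of 15 further kinds did not pass in the synovium. Of 18 neutrophil markers tested, 0 rose, 0 fell and 18 did not pass (adjusted over the list alone, 0 and 0), with a median of 0.28 (camera adjusted p = 0.766). Mmp9 had -0.41 ± 0.24 (adjusted p = 0.267). Among the bone marrow haematopoiesis genes, 0 of 18 rose and 0 fell, and 18 did not pass (adjusted over the list alone, 0 and 0); the median was 0.11 (camera adjusted p = 0.983). Their mean was -0.01, and Ngp, a neutrophil granule protein, had 0.26 ± 0.70. The IL-17 and IL-23 axis genes had a median of 0.43 over 8 tested members, of which 4 rose, 1 fell and 3 did not pass (adjusted over the list alone, 4 and 1; camera adjusted p = 0.0743). Cxcl5 rose by 5.71 ± 0.68, and Il23r had 93 counts in TNFdARE and 4 in WT (ratio 21.1, interval 7.98 to 79.2). Of 11 cytotoxic and NK cell markers tested, 1 rose, 5 fell and 5 did not pass (adjusted over the list alone, 1 and 6), with a median of -1.13 (camera adjusted p = 0.0743). Ccl5 rose by 3.12 ± 0.24 and Tbx21, the transcription factor T-bet, had -1.85 ± 0.30. Among the germinal centre and lymphoid follicle genes, 2 of 10 rose and 2 fell, and 6 did not pass (adjusted over the list alone, 3 and 3); the median was -0.46 (camera adjusted p = 0.584). Their mean was 0.25 and the test pointed up; Cxcl13 was among those that rose and Clu (-1.11 ± 0.15) among those that fell. The osteoclast genes had a median of -0.04 over 15 tested members, of which 2 rose, 1 fell and 12 did not pass (adjusted over the list alone, 2 and 1; camera adjusted p = 0.746). Their mean was -0.02 and the test pointed up. Tnfrsf11a, the receptor RANK, rose by 1.08 ± 0.10, and Tnfrsf11b, the decoy receptor osteoprotegerin, had -1.22 ± 0.18. Of 15 sublining fibroblast markers tested, 4 rose, 3 fell and 8 did not pass (adjusted over the list alone, 4 and 3), with a median of 0.18 (camera adjusted p = 0.296). Dpt rose by 0.99 ± 0.12 and Col14a1 by 1.14 ± 0.19. Among the extracellular matrix and fibroblast activation genes, 8 of 18 rose and 3 fell, and 7 did not pass (adjusted over the list alone, 8 and 3); the median was 0.02 (camera adjusted p = 0.0871). Pdpn, podoplanin, rose by 2.03 ± 0.13 and Ccn2 had -1.85 ± 0.13. Without TNFdARE replicate 2 the IL-17 and IL-23 axis (adjusted p = 0.0359), cytotoxic (0.0115) and extracellular matrix lists (0.0106) passed, and without TNFdARE replicate 3 the cytotoxic list did (0.0283).

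The Wnt and BMP antagonists had a median of -0.58 over 15 tested members, of which 2 rose, 6 fell and 7 did not pass (adjusted over the list alone, 3 and 6; camera adjusted p = 0.0925). Wif1 had -0.81 ± 0.16 and Dkk3 rose by 0.69 ± 0.15, and with the replicate block the list passed (adjusted p = 0.0404). Of 12 nerve and Schwann cell markers tested, 0 rose, 2 fell and 10 did not pass (adjusted over the list alone, 0 and 2), with a median of -0.55 (camera adjusted p = 0.0871). That list passed with the block too (adjusted p = 0.00692). Among the endothelial markers, 3 of 15 rose and 8 fell, and 4 did not pass (adjusted over the list alone, 3 and 9); the median was -0.29 (camera adjusted p = 0.066). Tek had -0.52 ± 0.07 and Sele, E-selectin, rose by 1.25 ± 0.19. Of 5 skin keratinocyte genes tested, 1 rose, 2 fell and 2 did not pass (adjusted over the list alone, 1 and 3), with a median of -0.55 (camera adjusted p = 0.121). Krtdap had -2.05 ± 0.25 and Sbsn -0.55 ± 0.12. The plasma cell markers had a median of -0.28 over 15 tested members, of which 0 rose, 1 fell and 14 did not pass (adjusted over the list alone, 0 and 0; camera adjusted p = 0.766). Among the red blood cell genes, 0 of 9 rose or fell (adjusted over the list alone, 0 and 0), with a median of -0.35 (camera adjusted p = 0.746). Hbb-bs had -0.44 ± 0.74. Of 14 immediate early and heat shock genes tested, 1 rose, 0 fell and 13 did not pass (adjusted over the list alone, 0 and 0), with a median of 0.09 (camera adjusted p = 0.697). The endothelial list passed without TNFdARE replicate 1 (adjusted p = 0.0189) or WT replicate 2 (0.0210), the nerve list without TNFdARE replicate 3 (0.0155) or WT replicate 2 (0.00966), and the immediate early list without WT replicate 1 (2.54e-04).

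All 20 synovium list calls but the one of TNF and NF-kB target genes ended with an estimated correlation. With fry those of skeletal muscle (adjusted p = 0.0669) and oxidative phosphorylation (0.14) ended too, while the IL-17 and IL-23 axis (0.00624), cytotoxic (0.0443), Wnt and BMP antagonist (0.00572) and keratinocyte lists (0.0347) passed. With all 12 libraries the cytotoxic, extracellular matrix and endothelial lists passed (0.0375, 0.0375 and 0.0134). Without TNFdARE replicate 3 the counts of genes were 1278 and 863, without WT replicate 3 they were 1265 and 952, and without WT replicate 1 they were 1501 and 1099; of the 65 named called genes, 58, 60 and 57 were kept without TNFdARE replicates 1, 2 and 3 and 62, 59 and 55 without WT replicates 1, 2 and 3. With the muscle level as a covariate, an alternative added after the data were seen, 431 genes rose and 123 fell and 33 of the named called genes were kept.

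**Figure D2:**
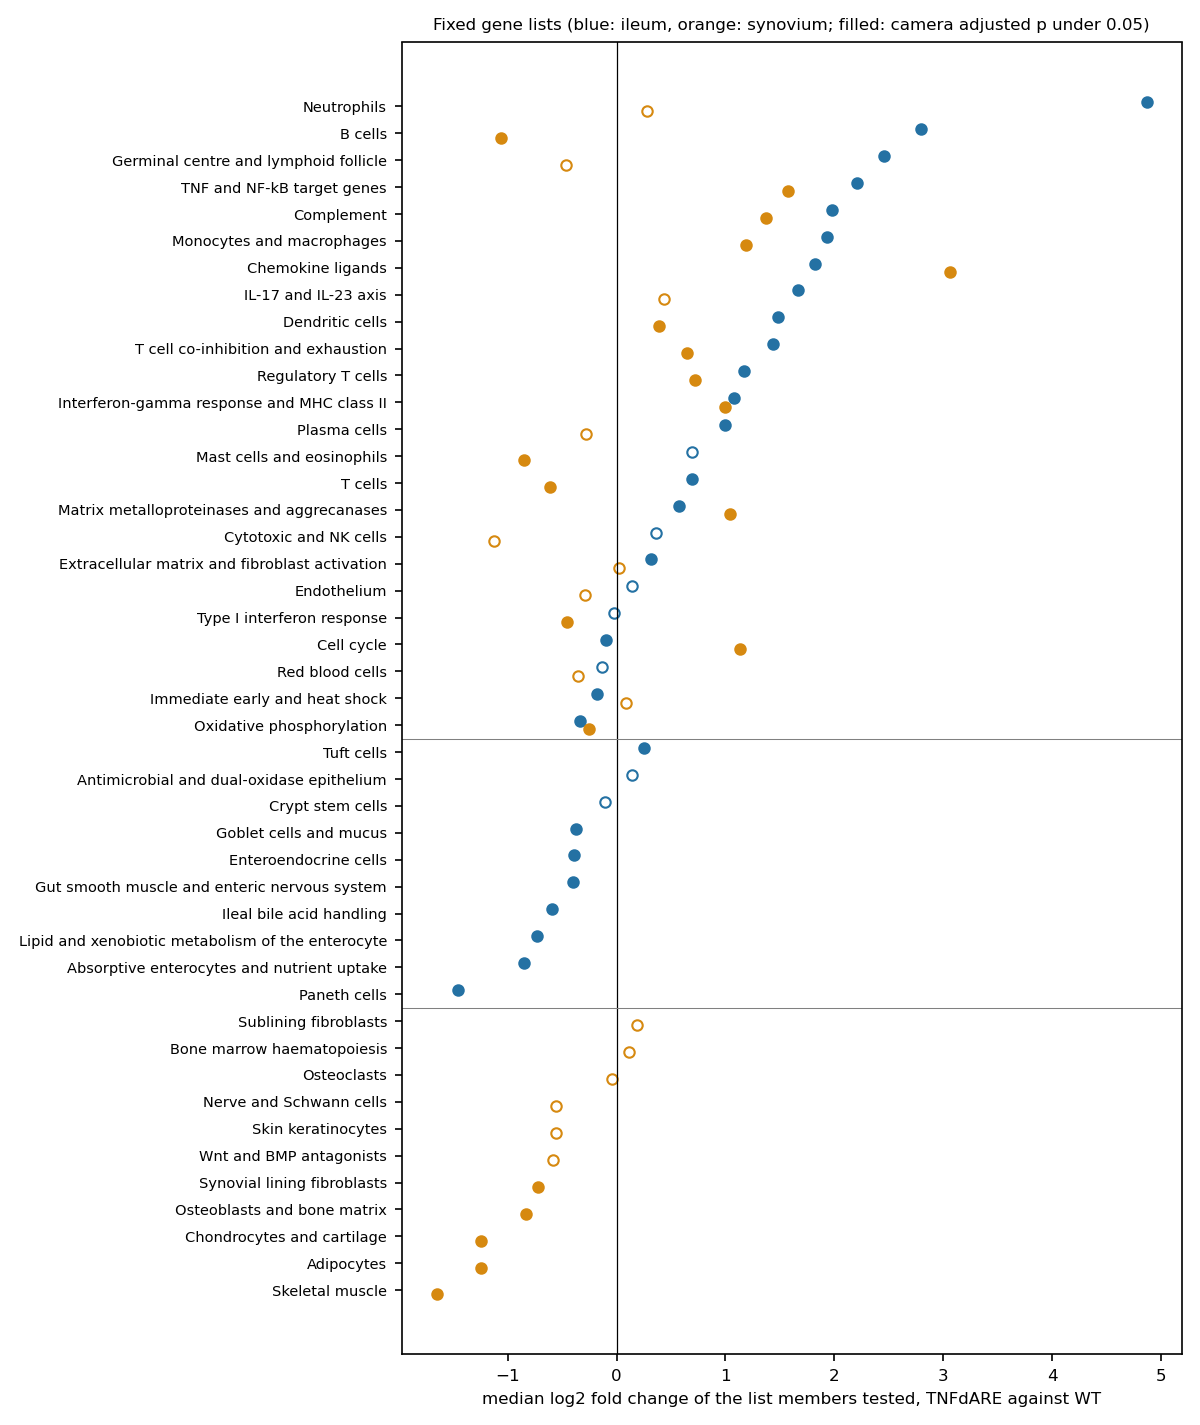
Median log2 fold change of TNFdARE over WT for each fixed gene list in ileum and in synovium. Filled points had a camera adjusted p under 0.05 with the preset correlation, which held for 27 of 34 lists in the ileum and 20 of 35 in the synovium. Neutrophils had 4.86 in ileum and 0.28 in synovium, which are changes and not levels.

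The third comparison asked how far both tissues shared their changes. Of 14211 genes tested in both, 280 rose in both tissues, where 84.7 would be expected from independent lists, and 37 were lower in both, where 20.9 would be expected. A further 39 rose in the ileum and fell in the synovium (62.9 expected) and 28 did the opposite (28.2 expected). Genes that rose in both included Cxcl5 (6.39 in ileum and 5.71 in synovium), Saa3 (5.70 and 8.51), Ccl2 (4.05 and 6.45) and C3 (4.72 and 3.35). Across genes, the log2 fold changes had a Pearson correlation of 0.300 and a Spearman correlation of 0.221; genes are not independent replicates, so no p is given for the overlap or the correlations. With the replicate block 453 genes rose in both, 57 fell in both and 108 went in opposite directions, against 280, 37 and 67. Without ileum TNFdARE replicate 2, an alternative added after the data were seen, these counts were 841, 392 and 331. Other libraries were left out after the data were seen as well: without ileum TNFdARE replicate 3 or any ileum WT library all 3 counts were 0, without ileum TNFdARE replicate 1 they were 96, 11 and 23, without synovium TNFdARE replicate 3 they were 221, 24 and 39, and without synovium WT replicate 3 the opposite count was 41.

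**Figure D3:**
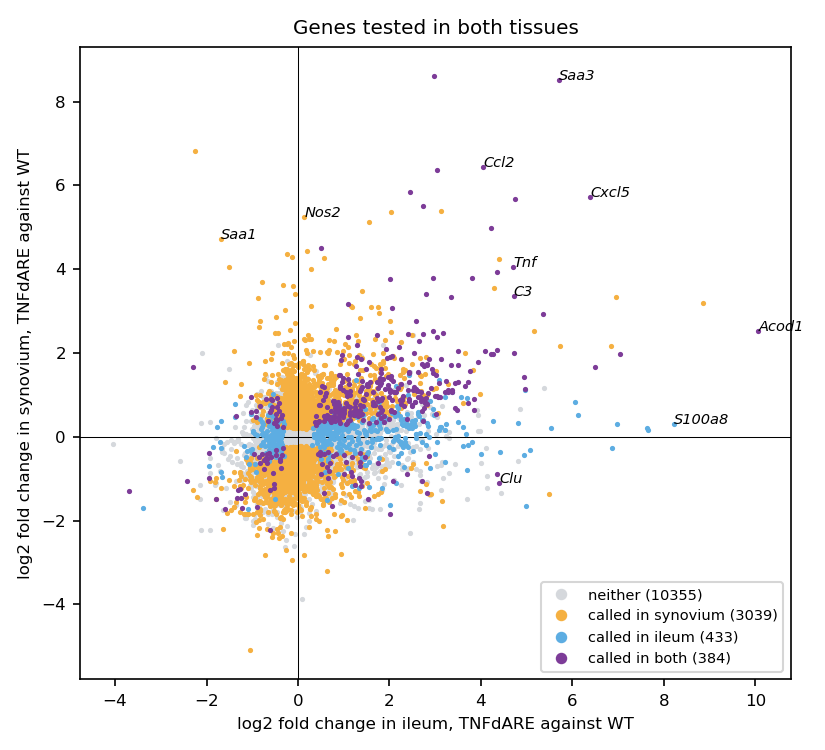
Log2 fold change of TNFdARE over WT in ileum (horizontal axis) and synovium (vertical axis), with a point for each of the 14211 genes tested in both tissues. Of these, 384 were called in both tissues, 433 in the ileum alone, 3039 in the synovium alone and 10355 in neither.

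The fourth comparison asked which TNFdARE effects differed between the tissues, by testing the synovium effect minus the ileum effect. Csf3r rose in the ileum and not in the synovium (5.07 and -0.30), a difference of -5.40 ± 0.68 (n = 3 per group, adjusted p = 0.00194), and Mmp9 differed by -4.43 ± 0.39 (adjusted p = 4.17e-04). Cx3cl1 rose in the synovium and had -0.18 in the ileum, a difference of 2.70 ± 0.18 with the smallest adjusted p of all genes (2.06e-04). Clu, which rose in the ileum, was lower in TNFdARE synovium, a difference of -5.52 ± 0.62 (adjusted p = 0.00129). Of 16964 genes tested, 896 were more positive and 1154 more negative in the synovium. For Tnf the difference was -0.67 ± 0.71 (adjusted p = 0.582), for Foxp3 -1.29 ± 0.80 (adjusted p = 0.315) and for Il10 -0.36 ± 0.89 (adjusted p = 0.838), and none of these passed.

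Within the same limits the 5 largest positive differences were in Saa1 (6.37 ± 0.91, adjusted p = 0.00328), Lyz1 (5.54 ± 0.68, adjusted p = 0.00169), Clrn3 (5.19 ± 0.94, adjusted p = 0.0119), Nos2 (5.08 ± 0.58, adjusted p = 0.00136) and Dok5 (4.74 ± 1.09, adjusted p = 0.0277). Nos2, the inducible nitric oxide synthase, had 5.24 in the synovium and 0.14 in the ileum. Saa1 had 387 counts in TNFdARE and 13 in WT synovium, a ratio of 27.0 (interval 15.6 to 51.3). Clrn3 and Dok5 were tested within a single tissue each, since Clrn3 had 10 counts in TNFdARE and 0 in WT synovium and Dok5 0 in TNFdARE and 14 in WT ileum. Within them the 5 largest negative differences were in Il13ra2 (-8.52 ± 1.65, adjusted p = 0.0163), S100a8 (-7.96 ± 1.69, adjusted p = 0.0173), Acod1 (-7.57 ± 2.00, adjusted p = 0.037), Il1f9 (-7.55 ± 1.46, adjusted p = 0.0114) and S100a9 (-7.45 ± 1.46, adjusted p = 0.012). Il13ra2, the decoy receptor of IL-13, had 120 counts in TNFdARE and 0 in WT ileum, and 207 counts in each genotype of the synovium. The ileum ratio was at least 33.2 by the lower bound of the exact interval of counting error. It was 41.4 with WT set at a floor of 3 counts over the group. The fitted difference of Il13ra2, like that of the other 4, depends on WT ileum counts near 0.

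Several leukocyte lists were more negative in the synovium. With animal as a block 4 of these calls ended: cytotoxic and NK cells (adjusted p = 0.182), the germinal centre (0.0501), plasma cells (0.0662) and dendritic cells (0.0796), and 20 of the 30 named called genes of the interaction were kept. Of 18 neutrophil markers tested, 0 were more positive, 8 were more negative and 10 did not pass (adjusted over the list alone, 0 and 11), with a median of -3.56 (camera adjusted p = 9.66e-09, and adjusted p = 0.613 with an estimated correlation). Among the B cell markers, 0 of 14 were more positive and 9 were more negative, and 5 did not pass (adjusted over the list alone, 0 and 13); the median was -4.53 (camera adjusted p = 1.34e-06, and adjusted p = 0.613 with an estimated correlation). Cr2, a complement receptor of B cells and follicular dendritic cells, differed by -6.88 ± 1.37 and Spib by -3.02 ± 0.68. The T cell markers had a median of -1.36 over 19 tested members, of which 0 were more positive, 3 were more negative and 16 did not pass (adjusted over the list alone, 0 and 9; camera adjusted p = 3.38e-05, and adjusted p = 0.613 with an estimated correlation). Cd28 differed by -2.46 ± 0.41. Of 11 germinal centre and lymphoid follicle genes tested, 1 was more positive, 3 were more negative and 7 did not pass (adjusted over the list alone, 1 and 7), with a median of -2.65 (camera adjusted p = 0.00192, and adjusted p = 0.613 with an estimated correlation). Ltb, lymphotoxin beta, differed by -3.15 ± 0.73. Among the plasma cell markers, 0 of 16 were more positive and 3 were more negative, and 13 did not pass (adjusted over the list alone, 0 and 7); the median was -1.17 (camera adjusted p = 0.00742, and adjusted p = 0.733 with an estimated correlation). Ighg2b differed by -5.42 ± 1.34 and Ighg2c by -4.70 ± 1.16. The dendritic cell markers had a median of -1.05 over 15 tested members, of which 1 was more positive, 5 were more negative and 9 did not pass (adjusted over the list alone, 1 and 8; camera adjusted p = 0.00553, and adjusted p = 0.613 with an estimated correlation). Batf3 differed by -1.92 ± 0.32 and Clec9a by -2.15 ± 0.47, both markers of conventional type 1 cells. Of 15 cytotoxic and NK cell markers tested, 0 were more positive, 4 were more negative and 11 did not pass (adjusted over the list alone, 1 and 6), with a median of -1.72 (camera adjusted p = 0.0318, and adjusted p = 0.733 with an estimated correlation). Klrb1c differed by -2.58 ± 0.58 and Tbx21 by -2.65 ± 0.58. Among the endothelial markers, 0 of 15 were more positive and 4 were more negative, and 11 did not pass (adjusted over the list alone, 0 and 5); the median was -0.49 (camera adjusted p = 0.00115, and adjusted p = 0.613 with an estimated correlation). Pecam1 differed by -0.76 ± 0.16 and Cdh5 by -0.64 ± 0.12.

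Lists of 3 kinds were more positive in the synovium. Of 18 cell cycle genes tested, 8 were more positive, 0 were more negative and 10 did not pass (adjusted over the list alone, 15 and 0), with a median of 1.22 (camera adjusted p = 2.23e-12, and adjusted p = 0.613 with an estimated correlation). Cdk1 differed by 1.57 ± 0.29 and Tyms by 1.20 ± 0.22. Among the chemokine ligands, 2 of 20 were more positive and 1 was more negative, and 17 did not pass (adjusted over the list alone, 4 and 1); the median was 0.29 (camera adjusted p = 0.00115, and adjusted p = 0.613 with an estimated correlation). Cxcl13 differed by 3.30 ± 0.77. The immediate early and heat shock genes had a median of 0.53 over 14 tested members, of which 1 was more positive, 0 were more negative and 13 did not pass (adjusted over the list alone, 4 and 0; camera adjusted p = 0.00757, and adjusted p = 0.613 with an estimated correlation). Hsph1 differed by 2.04 ± 0.37. Of 19 regulatory T cell markers tested, 0 were more positive, 0 were more negative and 19 did not pass (adjusted over the list alone, 0 and 0), with a median of -0.74 (camera adjusted p = 0.199). Among the T cell co-inhibition and exhaustion genes, 0 of 13 were more positive and 2 were more negative, and 11 did not pass (adjusted over the list alone, 0 and 3); the median was -0.96 (camera adjusted p = 0.0591). The TNF and NF-kB target genes had a median of -0.06 over 20 tested members, of which 2 were more positive, 2 were more negative and 16 did not pass (adjusted over the list alone, 4 and 3; camera adjusted p = 0.304). Their mean was 0.18 and the test pointed up. Of 20 markers of monocytes and macrophages tested, 0 were more positive, 3 were more negative and 17 did not pass (adjusted over the list alone, 0 and 4), with a median of -0.72 (camera adjusted p = 0.0542). Among the complement genes, 2 of 15 were more positive and 4 were more negative, and 9 did not pass (adjusted over the list alone, 4 and 6); the median was -0.77 (camera adjusted p = 0.269). The IL-17 and IL-23 axis genes had a median of -0.88 over 12 tested members, of which 1 was more positive, 3 were more negative and 8 did not pass (adjusted over the list alone, 2 and 4; camera adjusted p = 0.492). Of 19 interferon-gamma response and MHC class II genes tested, 0 were more positive, 1 was more negative and 18 did not pass (adjusted over the list alone, 0 and 0), with a median of -0.25 (camera adjusted p = 0.72).

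Among the type I interferon response genes, 0 of 19 were more positive and 0 were more negative, and 19 did not pass (adjusted over the list alone, 0 and 0); the median was -0.51 (camera adjusted p = 0.251). The mast cell and eosinophil markers had a median of -0.89 over 14 tested members, of which 0 were more positive, 2 were more negative and 12 did not pass (adjusted over the list alone, 0 and 3; camera adjusted p = 0.251). Of 18 extracellular matrix and fibroblast activation genes tested, 2 were more positive, 4 were more negative and 12 did not pass (adjusted over the list alone, 4 and 5), with a median of -0.03 (camera adjusted p = 0.869). Their mean was -0.12 and the test pointed up. Among the matrix metalloproteinases and aggrecanases, 0 of 16 were more positive and 1 was more negative, and 15 did not pass (adjusted over the list alone, 0 and 1); the median was 0.13 (camera adjusted p = 0.987). Their mean was -0.20 and the test pointed down. The oxidative phosphorylation genes had a median of 0.06 over 16 tested members, of which 0 were more positive, 0 were more negative and 16 did not pass (adjusted over the list alone, 0 and 0; camera adjusted p = 0.199). Of 9 red blood cell genes tested, 0 were more positive, 0 were more negative and 9 did not pass (adjusted over the list alone, 0 and 0), with a median of -0.31 (camera adjusted p = 0.64). Their mean was 0.28 and the test pointed up. All 11 interaction list calls ended with an estimated correlation. Without ileum TNFdARE replicate 2 the counts of genes were 1814 more positive and 1692 more negative, without replicate 3 they were 472 and 553, and without an ileum WT library the more negative count was 513, 528 or 484. Without synovium TNFdARE replicate 3 the counts were 499 and 516, without WT replicate 3 they were 532 and 639, and without WT replicate 1 the more negative count was 695. The balance of directions moved with the scaling, the measure and the filter: it was 896 to 1154 here, 1115 to 1011 with RLE factors, 626 to 1380 with library size only, 1360 to 968 with log2(FPKM + 1) and 1200 to 1014 with the filter of 10 counts, and the median over all genes was -0.08.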

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

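The 100 regroupings of libraries in this part were planned before the results were seen, and the 32 regroupings within replicate numbers and the list test without ileum TNFdARE replicate 2 were chosen after. Each result here stands out because the TNFdARE effect differed between synovium and ileum in a direct test of the difference; values are log2 differences, synovium minus ileum. The list medians were -3.56 for neutrophils, -4.53 for B cells, -2.65 for the germinal centre and lymphoid follicle, -1.36 for T cells, -1.72 for cytotoxic and NK cells, -1.17 for plasma cells, -1.05 for dendritic cells, -0.49 for endothelium, 1.22 for the cell cycle, 0.29 for chemokine ligands and 0.53 for immediate early and heat shock genes. All 11 lost their call with an estimated correlation (adjusted p from 0.613 to 0.733), and the cytotoxic (adjusted p = 0.182), germinal centre (0.0501), plasma cell (0.0662) and dendritic cell lists (0.0796) lost it with animal as a block too.

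Among single genes the differences were -8.52 for Il13ra2, -7.96 for S100a8, -7.57 for Acod1, -7.55 for Il1f9, -7.45 for S100a9, -6.88 for Cr2, -5.52 for Clu, -5.42 for Ighg2b, -5.40 for Csf3r, -4.70 for Ighg2c, -4.43 for Mmp9, -3.15 for Ltb, -3.02 for Spib, -2.65 for Tbx21, -2.58 for Klrb1c, -2.46 for Cd28, -2.15 for Clec9a, -1.92 for Batf3, -0.76 for Pecam1 and -0.64 for Cdh5. On the other side they were 6.37 for Saa1, 5.54 for Lyz1, 5.19 for Clrn3, 5.08 for Nos2, 4.74 for Dok5, 3.30 for Cxcl13, 2.70 for Cx3cl1, 2.04 for Hsph1, 1.57 for Cdk1 and 1.20 for Tyms. With animal as a block 10 of the 30 named called genes lost their call. Dok5 turned direction with log2(FPKM + 1) (-0.19) and rests on 0 counts in TNFdARE and 14 in WT ileum, and Clrn3 on 10 and 0 in the synovium.

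Of 100 regroupings of the libraries within each tissue, the real one included, 1 gave as many interaction genes: the real grouping called 2050 and the highest other 1518. Each other grouping mixed the genotypes within a tissue. That removes the effect of genotype itself, not only its difference between tissues, and widens the spread. The regroupings also take the libraries of a tissue as freely exchangeable and the tissues as coming from different animals. They therefore cannot decide whether chance gave the count of genes with a different effect. Replicate numbers paired the libraries of a tissue, and of the 32 regroupings that exchange genotypes only within a number, 2 gave as many: the real one and the exchange of genotype in the whole of 1 tissue (4029). That exchange keeps both genotypes whole and adds their effects, so its count is no chance value and the 32 decide nothing; the highest of the other 30 called 1324. With animal as a block the count was 1102, with 48.00% of the 2050 called again. For the lists chance cannot be excluded, since 52 of the 100 called as many as the real 11 and the highest other called 20. Without ileum TNFdARE replicate 2 the same 11 lists passed and 7 more did.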

How the results depend on the processing

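Alternatives were planned, except those named above as added after seeing the data. Causes were not tested unless stated. Synovium counts moved least: they stayed within 1.5 times of 2037 higher and 1676 lower except at an adjusted p under 0.01 (933 and 507), at 2-fold (613 and 643), with the muscle covariate (431 and 123) and without single libraries (1265 to 1670 and 863 to 1277). Ileum counts, 637 higher and 242 lower, were 1218 and 161 with library size only, where the median of all genes was 0.105; 1715 and 988 with DESeq2; 0 and 0 with limma-voom; 2 and 1 with log2(FPKM + 1), 0 and 0 with it over all genes, 138 and 53 with log2(FPKM + 0.1); 0 and 0 at an adjusted p under 0.01; 50 lower at 2-fold; 1827 and 895 with all 12 libraries; 0 and 0 with sex as covariate; and 0 to 2609 and 0 to 2024 without single libraries. The interaction counts, 896 more positive and 1154 more negative, were 1617 more positive with DESeq2, 746 more negative with limma-voom, 1360 more positive with log2(FPKM + 1) and 1353 with it over all genes, 253 and 230 at an adjusted p under 0.01, 337 and 733 at 2-fold, 509 and 593 with animal as a block, and 472 to 1814 and 484 to 1692 without single libraries.

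Genes higher in both, lower in both and opposite, 280, 37 and 67, were 689, 181 and 271 with DESeq2, 453, 57 and 108 with the replicate block, 0, 0 and 0 at an adjusted p under 0.01, 841, 392 and 331 without ileum TNFdARE replicate 2, 96, 11 and 23 without replicate 1, and 0, 0 and 0 without replicate 3 or any ileum WT library; without synovium TNFdARE replicate 3 they were 221, 24 and 39, and without synovium WT replicate 3 41 were opposite; with all 12 libraries 147 were lower in both and 198 opposite. Tnf in the ileum, 4.70, kept its direction but not its call with no filter (4.695, adjusted p = 0.0624), limma-voom (4.48), log2(FPKM + 1) (3.53, also over all genes) and sex as covariate (4.71), with adjusted p from 0.0521 to 0.0999 there, and ran from 4.11 to 5.12 without single libraries. With an estimated correlation ileum lists fell from 17 higher and 10 lower to 0 and 0, synovium lists from 10 and 10 to 1 and 0, and interaction lists from 3 and 8 to 0 and 0. With fry the ileum had 3 and 0; with animal as a block 4 interaction lists were lower, and without ileum TNFdARE replicate 2, 14.

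Reversed values, none of them past the threshold in its alternative except the first, were the antimicrobial and dual-oxidase list, whose test turned from down to up with the replicate block (median 0.0036, adjusted p = 0.0265); Cela1 0.0534, Fabp6 0.0877 and Oasl2 0.0861 with library size only; Oasl2 0.0210 and Hbb-bs -0.0629 with log2(FPKM + 1), the same over all genes, and 0.0126 and -0.0567 with log2(FPKM + 0.1); Ngp -1.22 with the muscle covariate; and for the interaction Il10 0.18 and Dok5 -0.19 with log2(FPKM + 1), the same over all genes, and Il10 0.52 with log2(FPKM + 0.1). Without single libraries Olfm4 ran from -0.12 to 0.25, Fabp6 from -0.20 to 0.20, Oasl2 from -0.28 to 0.53, Cela1 from -0.19 to 0.0598 and Hbb-bs from -0.20 to 0.48 in the ileum; Ngp from -0.49 to 0.88 and Hbb-bs from -1.08 to 0.46 in the synovium; and the interaction of Tnf from -0.98 to 0.0169 and of Il10 from -0.84 to 0.11. Depth limited Il10, which had 1 to 20 counts per library, and the fold changes of genes near 0 counts in WT.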

Other observations

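The genes in the next 2 sentences were chosen after their values were seen. Genes lower in TNFdARE in both tissues included Tsc22d3, a glucocorticoid-induced gene (-0.90 in ileum and -1.67 in synovium), Usp2, a deubiquitinase with circadian expression (-1.34 and -1.46), Timp3, an inhibitor of metalloproteinases (-0.54 and -0.87), and Car4, a carbonic anhydrase (-1.79 and -1.48). Genes that rose in the ileum and were lower in the synovium included Slc36a2 (4.36 and -0.90), Vnn3 (2.83 and -1.33), Mfge8, a bridging protein for the uptake of apoptotic cells (2.87 and -0.45), and Scd1, stearoyl-CoA desaturase (1.24 and -1.15), with interaction adjusted p = 0.00113, 0.00232, 0.00136 and 0.00155. In the other direction B3gnt7 had -2.29 and 1.66 (interaction adjusted p = 0.00159). Il17a, also chosen after its values were seen, had 49, 16 and 48 counts in TNFdARE and 1, 5 and 9 in WT ileum (2.82 ± 0.68, adjusted p = 0.0577, which did not pass), and at most 1 count in any synovium library.

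The tests in the next 3 paragraphs were chosen after seeing the results, apart from the prediction for the muscle covariate and the regroupings. With 6 libraries only 10 splits exist per tissue, too few for a share under 0.05: the real split called 879 ileum and 3713 synovium genes and the highest other 0 in both, including the splits that part all 3 replicate numbers. For lists the real split called 27 in the ileum, against 25 for the highest other, and 20 in the synovium, against 21; 1 of 10 ileum splits and 3 of 10 synovium splits called as many as the real. Of 100 pairs of splits, 1, the real pair, gave as many genes called in both tissues (384, highest other 0). This adds nothing to the splits of each tissue, since no other split called a gene to share.

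Within 2 Mb of Tnf, 22 of 160 tested ileum genes were called, 13.8% against 5.59% elsewhere (Fisher's exact test, two-sided, p = 1.04e-04), although 49 of 1130 other windows of that width had as high a share. Reads shared between gene copies are consistent with this, since the share was 6.90% among genes with other names, near that elsewhere, and 31.8% among H2, Btnl and predicted gene names. In the synovium 24.16% of 149 tested genes there were called, against 23.79% elsewhere, and of the 22 genes 8 were tested in the synovium, 6 with the same direction and 2 called. A strain variant carried along with the modified locus, which both tissues would hold, may also contribute: it predicts changes of full size in TNFdARE replicate 2, and H2-Bl, H2-Q1, H2-Q2 and A930015D03Rik had them. The median over the 22 genes lay at percentile 63.4 of random sets of called genes, so this explanation cannot be told apart from the general effect of genotype.

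TNFdARE replicate 2 of the ileum lay near WT. A mislabelled WT sample is argued against by Tnf, 6.53 times the highest WT library. WT RNA mixed into a library otherwise like the other TNFdARE replicates would keep the same share of every shift. Complement genes kept a median 0.337 and B cell genes 0.0403 of the shift of the other replicates, with a gap of 0.214 between their quartiles. These values argue against mixing into such a library only. They cannot exclude mixing where the animal's own profile differed from the others. An earlier comparison with the genes beside Tnf had not separated mislabelling and mixing. A lesser or earlier inflammation, or less lymphoid tissue in the piece taken, remains a hypothesis that these data do not test.

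Genes lower in TNFdARE synovium moved with the muscle level. With it as covariate the lower quartile of the share of the fold change left was 0.604 over the 1675 lower genes outside the muscle list; their median went from -0.83 to -0.63 while the median SE went from 0.161 to 0.251, so both a wider error and a smaller fold bore on the calls that ended. Muscle amount is thus argued against as the whole source. Adipocyte genes fell more than endothelial genes (quartile gap 0.669), which cannot decide on dilution by entering cells, since 3 of 15 endothelial genes rose. Muscle amount, loss of fat and joint tissue, and dilution remain hypotheses, and other differences in dissection were not tested.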
